A study of Mus musculus with 6 samples.

How the data were processed

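Gene expression was measured in the left ventricle of male C57BL/6 mice aged 12 to 16 weeks. There were 3 samples from mice homozygous for a targeted disruption of Akt2 and 3 from wild type mice, each hybridised as biotin-labelled cRNA to its own Affymetrix mouse array. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples.

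The deposited values are intensities, 1 linear signal for each of 45101 probe sets on each array. Per the submitters' processing notes they were computed with MAS5, the algorithm that combines the perfect-match and mismatch probes of a probe set into a signal. The version and settings of MAS5 are not given in the sources used here, and detection calls were not used here. In the deposited table the mean signal without the extremes was 499.8 on every array, so the arrays had been scaled by 1 factor each, and median signals still differed between arrays. That scaling was kept. A single factor leaves differences in the shape of the signal distribution between arrays in place.

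The 64 control probe sets were left out of the tests and used to look for technical differences between the arrays. Signals were put on the scale log2(signal + 21.7), where 21.7 is the 20th percentile of all values, so a fold change is on that scale and understates the change of dim genes. The 22519 probe sets with a mean log2 value at or above the median, 6.868, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold errors are the moderated standard errors (SE) of limma on the log2 scale, and errors of signals are standard deviations (SD).

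Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and were left out of the gene-level test, and 9160 are unnamed here. The gene-level test took the brightest probe set of each of 11075 genes. Of these, 11048 were matched to a RefSeq gene table of assembly GRCm38.p6, all under the symbol the platform annotation gives. The array annotation names no build, so that table was used only for which genes neighbour each other.

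Before the data were examined, 40 gene lists were fixed: 26 of pathways and 14 of markers of cell types the tissue could hold. Of these, 35 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, each list against all other tested genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The genes named were fixed by rule: Akt1, Akt2 and Rab4a whatever their result, the 10 genes with the lowest unadjusted p among those at least 1.5-fold higher and the 10 among those at least 1.5-fold lower, since too few genes passed the threshold, and up to 4 members of each list described, by lowest unadjusted p. Rab4a and the genes of beta-adrenergic signalling were listed because a report on these mice is known to have dealt with them, so those lists are not independent evidence.

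The labels number the samples 1 to 3 in each genotype. Over the tested probe sets, the deviations of same-numbered arrays from their genotype means correlated at 0.61, 0.45 and 0.39 for numbers 1, 2 and 3. The unlike numbers 2 and 3 gave 0.44 and 0.36, and the difference between arrays 2 and 3 in the wild type correlated at 0.03 with that in the knockout. The labels do not say what the number stands for. Fits with the replicate number as a block are given where they change a call or a count.

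By the control probe sets, the replicate 1 arrays of both genotypes stood apart from the other 4. They are called a batch here, though the labels name none. After this was seen, 3 alternatives were added: a fit with that batch as a block, a fit of the other 4 arrays alone, and the batch block together with a trended, robust variance estimate. The alternatives planned before the data were examined were other pseudocounts, filters, scalings and variance estimates, the replicate block, another threshold, the mean of all probe sets of a gene, other list tests, and leaving out each array in turn. The fits without an array have no block and leave unequal shares of the batches in the genotypes. What changes in them can therefore come from the batch difference as well as from the array left out.

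The test was checked on simulated data with known changes added. These were drawn from the batch-block fit of the 22519 probe sets, with independent normal noise. Without a block it recovered 0% of log2 changes of 1, 51.5% of changes of 2 and 75.8% of changes of 3. With the batch block it recovered 64.7%, 100% and 100%, and 10 of its 186 calls were false. The simulated arrays held the batch difference that this block models. Its gain was therefore built in and does not measure its power in the real data. There Akt2, at log2 -2.69, had a limma adjusted p of 0.0963 over the genes with the batch block. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.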

Results

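Left ventricles of 3 Akt2 knockout and 3 wild type samples were compared on 6 arrays to find out which transcripts differ in the heart when Akt2 is missing. Akt2 is a serine/threonine kinase through which insulin acts on glucose uptake in muscle and fat. The median signal was between 88.4 and 91.2 in 4 arrays. It was 167.2 in wild type replicate 1 and 134.3 in knockout replicate 1.

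The replicate 1 arrays of both genotypes stood apart from the other 4. The poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, had median signals of 51 and 83 in wild type 1 and knockout 1, against 628.6 to 1015.2 in the other arrays. The 18S ribosomal RNA control probe sets had median signals of 82330 and 57275 in these 2 arrays, against 153 to 447. Within each batch the poly-A medians were also higher in the knockout, 83 against 51, and 1015.2 and 828.7 against 781.8 and 628.6. In the replicate 1 pair, other probe sets of these spike-ins, outside these medians, went both ways. PheX-3 had 22.5 in knockout 1 against 236.2 in wild type 1 and ThrX-M 13.3 against 91, while DapX-3 had 243.8 against 163.9. A genotype difference in the poly-A controls was thus seen steadily only in replicates 2 and 3. The Actb 3' to 5' ratio was higher in the knockout for each replicate number, 1.67 against 1.61, 1.44 against 1.34 and 1.48 against 1.40, while that of Gapdh was 0.81 against 0.90 in the replicate 1 pair and 0.73 against 0.74 in the others. No control probe set of the 64 had all 3 knockout arrays on one side of all 3 wild type arrays. The poly-A and 18S controls differed far more between the batches than between the genotypes. For them such an overlap was all but fixed in advance, so it excludes no technical difference between the genotypes. The genotype comparisons were not adjusted for the differences between genotypes seen within a batch. Between these 2 arrays and the other 4, 7464 probe sets differed with genotype in the limma model, 4497 higher and 2967 lower in the replicate 1 arrays. Correlations of log2 signals were 0.982 to 0.986 within the 4 arrays, 0.94 between the replicate 1 arrays and 0.895 to 0.944 across, over probe sets, which are not independent replicates. Across, they were 0.895 to 0.905 for wild type 1 and 0.933 to 0.944 for knockout 1. Knockout 1 was thus about as close to knockouts 2 and 3 (0.943 and 0.944) as to wild type 1, and wild type 1 stood furthest apart. Each batch held both genotypes, so within-batch values are given beside the pooled ones: the replicate 1 pair has 1 array a genotype, and replicates 2 and 3 have 2.

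**Figure D1:**
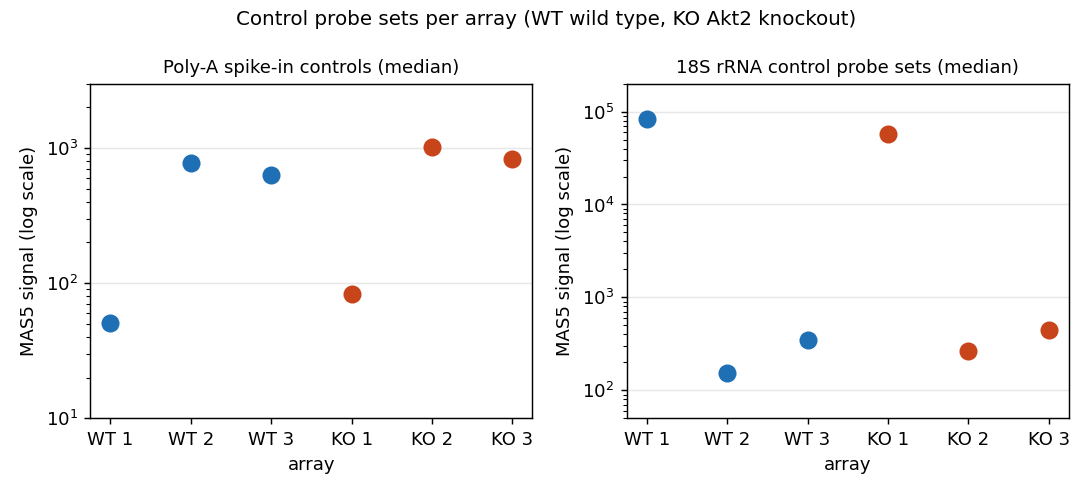
Median MAS5 signal (log axis) of the poly-A spike-in controls (left) and of the 18S ribosomal RNA control probe sets (right) in each of the 6 arrays, wild type in blue and Akt2 knockout in orange. The replicate 1 arrays lie at 51 and 83 for the spike-in controls and at 82330 and 57275 for 18S, apart from the other 4 arrays in both.

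Akt2 itself was low in every knockout array. Its brightest probe set had a signal of 375.9 ± 112 (SD, n = 3) in the knockout against 2476 ± 102 (SD, n = 3) in the wild type, a log2 difference of -2.69 (SE 0.24). A second Akt2 probe set had 81.07 ± 25.7 against 1369 ± 846 (log2 -3.63, SE 0.427), and a further one had 74.77 ± 10.3 against 187.2 ± 32.2 (log2 -1.11, SE 0.199). Which part of the transcript each probe set reads, relative to the disrupted part, is not given in the sources used here. The limma adjusted p of Akt2 over all 11075 genes was 0.0638, above the threshold of 0.05, and 0.0963 with the batch block. Adjusted over the list alone, that of 23 tested Akt and insulin signalling genes, it was 0.000264. Akt1, a closely related kinase, had 2284 ± 26.3 against 2678 ± 35.2 (log2 -0.23, SE 0.143). All 3 knockout arrays were below all 3 wild type arrays, but its adjusted p was 1. Its other tested probe sets gave -0.40 (SE 0.166) and -0.68 (SE 0.449).

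Beyond Akt2, and among genes tested by their brightest probe set naming 1 gene, Wdfy1 and Blvrb had the lowest unadjusted p in limma without a block, followed by Klhl32, Sh3gl2, Caap1, Nnt and Cpa3. At the level of probe sets, a probe set shared by Plac9a, Plac9b and Gm9780 (log2 -1.50, SE 0.205) came before Blvrb, and one of Pisd-ps3 (1.98, SE 0.327) before Klhl32. These last 2 lie outside the rule for named genes and were chosen after their values were seen. Wdfy1, whose product binds phosphatidylinositol 3-phosphate on early endosomes, had a signal of 711.7 ± 130 in the knockout against 130.7 ± 15.9 in the wild type (log2 2.26, SE 0.197, n = 3 each). Its other tested probe sets gave 2.74 (SE 0.613), 1.87 (SE 0.246) and 0.57 (SE 0.488). Blvrb, biliverdin reductase B, had 1704 ± 147 against 806.7 ± 28.5 (log2 1.06, SE 0.154). Nnt, the mitochondrial transhydrogenase that makes NADPH, had 26590 ± 3940 against 13220 ± 797 (log2 1.00, SE 0.176), and its other tested probe set had 11240 against 5206. Rab4a, a small GTPase of endosomal recycling, had 625.4 ± 27.1 against 227.1 ± 113 (log2 1.47, SE 0.305), with a log2 difference of 0.74 in the replicate 1 pair and 1.83 in replicates 2 and 3. Its other probe set gave 1.55 (SE 0.299), with 1.49 in the replicate 1 pair and 1.58 in replicates 2 and 3.

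In the planned limma test, 0 of 22519 probe sets and 0 of 11075 genes had an adjusted p under 0.05. Unadjusted p was under 0.05 for 453 probe sets and 240 genes, where uniform p-values would give 1126 and 554. This fit leaves the difference between the batches in its error, so the shortfall does not show that the genotypes differ less than chance gives. With the batch block, unadjusted p was under 0.05 for 1750 probe sets and 921 genes, and Wdfy1 rose (adjusted p = 0.0146, against 0.0638 without). It was the only gene to pass in that fit, with 1 probe set. Without a block, Akt2 and Wdfy1 passed when a stricter filter on low signals was used (adjusted p = 0.0286 each). Over its alternatives Wdfy1 had an adjusted p between 0.000849 and 0.806. With the replicate block no gene passed, and 1267 probe sets had an unadjusted p under 0.05. The batch block with the trended, robust variance estimate called 5 genes: Akt2 fell (adjusted p = 0.000849), while Wdfy1 (0.000849), Blvrb (0.00828), Nnt (0.00986) and Nr4a1 (0.00986) rose. At the level of probe sets that fit called 13, among them the Rab4a probe set with log2 1.55 (limma adjusted p = 0.011). The brightest Rab4a probe set did not pass in it (0.104, and 0.125 at the gene level).

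By the descriptive measure, 70 probe sets had an unadjusted p under 0.01 and at least a 1.5-fold difference, 35 higher and 35 lower in the knockout. The count was 194 with the replicate block (75 higher, 119 lower), 234 with the batch block (90 and 144) and 332 in replicates 2 and 3 alone (142 and 190). It was 168 without wild type replicate 1 (92 and 76), 67 without knockout replicate 1 (22 and 45), 44 without knockout replicate 2 and 45 without knockout replicate 3. The fits without an array leave unequal shares of the batches in the genotypes, so these last counts mix in the batch difference. Uniform p-values would give 225 probe sets with an unadjusted p under 0.01, whatever the fold. By that p alone, limma gave 70 without a block and 205 with the replicate block. It gave 336 with the batch block and 442 in replicates 2 and 3 alone.

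The other genes named by rule on the higher side were Klhl32 (log2 0.95), Sh3gl2 (1.54), Fam102a (0.77), Trmt61b (0.82), Lgi1 (0.72) and Apex2 (0.78). Sh3gl2, which encodes endophilin A1, had 203.3 ± 81.2 against 52.87 ± 5.29. Other tested probe sets were weaker: Sh3gl2 0.69 and 0.27, Fam102a 0.53, Klhl32 0.36, Lgi1 0.48, Apex2 0.07 and, of the lower genes that follow, Zfp975 -0.51. On the lower side were Cpa3 (-1.47), Caap1 (-1.10), E130119H09Rik (-1.56), Zfp932 (signal 105.1 against 225.7), Meox1 (-0.93), Zfp975 (-0.93), Arid3a (-0.92), Lad1 (-0.82) and Ramp1 (-0.79). Cpa3, a carboxypeptidase of mast cells, had 51.13 ± 14.5 in the knockout against 181.9 ± 57.5. Meox1, a homeobox transcription factor, had 480.6 ± 97 against 929.9 ± 117, and Ramp1, a subunit of the calcitonin gene-related peptide receptor, had 614.6 ± 59.9 against 1084 ± 160. In all 21 named genes every knockout array lay on one side of every wild type array, as did 7.5% of all genes. Arrays in random order would give 10%, but the replicate 1 arrays stand apart, so that share is no fair benchmark. Apart from the genes fixed beforehand, the named genes were picked for a low p and a 1.5-fold difference in these same arrays. Their separation follows largely from that choice. The adjusted p of each gene in this paragraph was 1 without a block, and between 0.223 and 0.561 with the batch block.

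**Figure D2:**
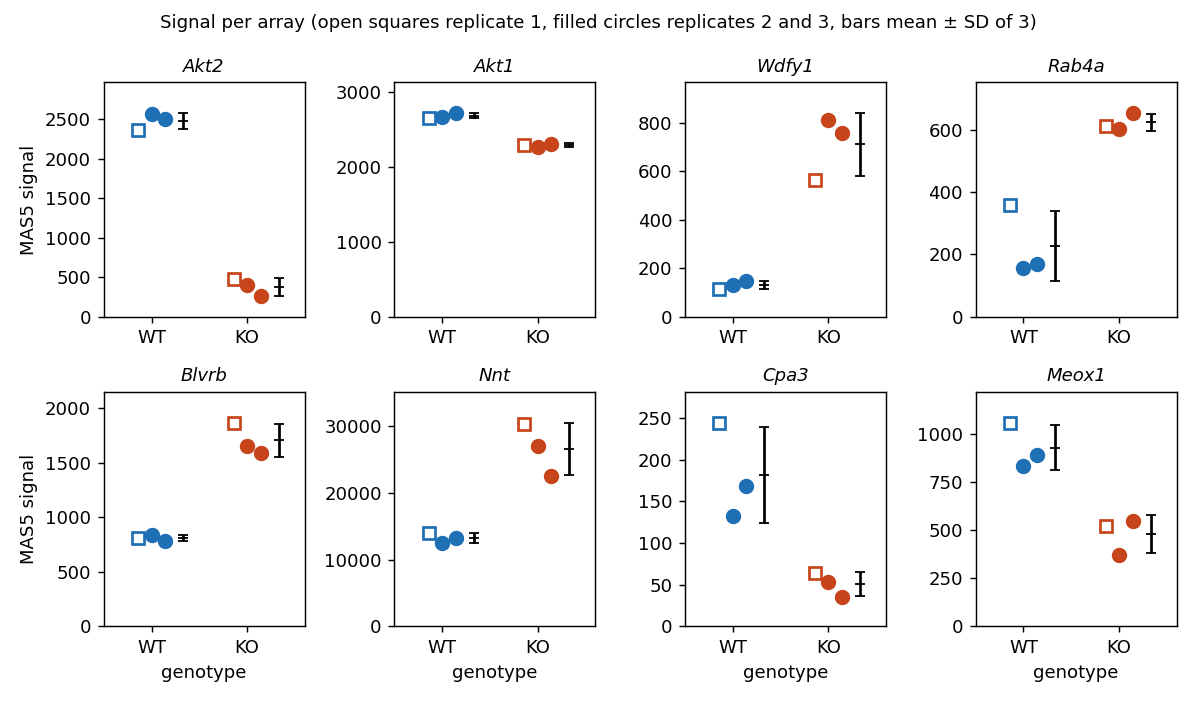
MAS5 signal (linear axis from 0) of 8 named genes in each array by genotype (WT wild type, KO knockout), with open squares for replicate 1, filled circles for replicates 2 and 3, and bars for the mean ± SD of 3 arrays. The groups do not overlap in any panel; Akt2 averages 2476 against 375.9 and Wdfy1 130.7 against 711.7.

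Among the 35 gene lists, only that of the unfolded protein response, the chaperones and sensors of the endoplasmic reticulum, passed the planned camera test, and it did not pass the other list tests. Of its 24 tested members, 16 were lower in the knockout and 8 higher, with a median log2 difference of -0.14. The camera test gave an adjusted p of 0.0022, against an adjusted p = 0.40 with an estimated correlation and 0.16 by fry. Pdia6, a protein disulfide isomerase, had 1694 ± 65.5 in the knockout against 2513 ± 363 in the wild type (log2 -0.55, SE 0.169, n = 3 each). Sdf2l1 had -0.59 (SE 0.206), Creld2 -0.60 (SE 0.212) and Manf, a secreted protein of the endoplasmic reticulum, -0.45 (SE 0.179), and in these 4 genes all knockout arrays were below all wild type arrays. No member passed over all genes and 0 adjusted over the list alone, where Pdia6 had 0.203; 4 had an unadjusted p under 0.05. The median was -0.08 in the replicate 1 pair and -0.19 in replicates 2 and 3. The call was lost without wild type replicate 3 (adjusted p = 0.258) and without the filter on low signals (0.0991), where the medians, -0.123 and -0.143, stayed near the -0.143 of the planned test.

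Over all lists, 0 of 697 list members passed adjusted over all genes and 2 adjusted over the list alone, Akt2 and Rab4a. With the preset correlation the replicate block called 3 lists, the batch block 4 and replicates 2 and 3 alone 8. With an estimated one the batch block and replicates 2 and 3 called 0, and fry with the batch block called 1. The median had opposite signs in the 2 batches in 23 of the 35 lists. In 12 lists, none past the threshold, the median, the mean and the direction of the test differed in sign.

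Markers of macrophages and monocytes were lower in the knockout in 14 of 16 genes, with a median log2 difference of -0.21. Examples were Csf1r, the receptor for colony-stimulating factor 1, with 4390 ± 585 against 5280 ± 465 (log2 -0.27, SE 0.175), Lyz2 (-0.43, SE 0.318) and Ccr2 (-0.57, SE 0.345). The camera adjusted p was 0.061, which missed the threshold. It was 0.0021 with the replicate block and 0.0023 with the batch block, but 1 with the batch block and an estimated correlation. With an estimated correlation and no block it was 0.99. By fry the adjusted p was 0.99 without a block and 0.66 with the batch block. Without a block, 0 of the 16 genes had an unadjusted limma p under 0.05. In 0 of them did all knockout arrays lie on one side of all wild type arrays. The median was -0.29 in the replicate 1 pair and -0.17 in replicates 2 and 3. Without knockout replicate 1 it was 0.03, and it passed at -0.47 without knockout replicate 3 (adjusted p = 6.19e-06) and at -0.375 without wild type replicate 1 (0.000711). Each fit without an array leaves unequal shares of the batches in the genotypes, so these values mix in the batch difference.

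Endothelial markers were lower in 13 of 17 genes, with a median of -0.12. Vwf, von Willebrand factor, had 818 ± 63.9 against 1026 ± 110 (log2 -0.32, SE 0.165), and Aqp1, a water channel, had -0.27 (SE 0.166). Tek, the angiopoietin receptor, had -0.22 (SE 0.146), and Pecam1 had -0.19 (SE 0.148). The camera adjusted p was 0.064, against 0.048 with the replicate block, 0.031 with the batch block and 0.78 with an estimated correlation. By fry it was 0.15 without a block and 0.044 with the batch block, where the estimated correlation gave 1. Medians within batches were -0.11 and -0.15. The other cell types did not pass: fibroblast markers had a median of 0.04, smooth muscle and pericytes 0.01, neutrophils -0.07, adipocytes 0.04, atrial myocytes 0.10, skeletal muscle -0.09, and Schwann cells and neurons 0.14, with adjusted p of 0.97 in all but the last, which had 0.89.

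Ribosomal protein genes were lower in 21 of 22 members, by a median of -0.08, with Rps18 at 22890 ± 1090 against 26180 ± 1730 (log2 -0.19, SE 0.152) and Rps6 at -0.19 (SE 0.155). The camera adjusted p was 0.064, against 0.044 with the batch block and 0.99 with an estimated correlation. The median was -0.20 in the replicate 1 pair and -0.04 in replicates 2 and 3, and without knockout replicate 3 the list passed at -0.13 (adjusted p = 0.00876).

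Genes of insulin signalling other than Akt2 did not pass. Irs2, an insulin receptor substrate, had 261.4 ± 220 in the knockout against 71.13 ± 30.5 (log2 1.39, SE 0.522), with 3.05 in the replicate 1 pair and 0.57 in the others. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, had 2518 ± 154 against 1812 ± 507 (log2 0.50, SE 0.227). The Akt and insulin signalling list had a median of 0.01 (adjusted p = 0.97). FoxO target genes had a median of -0.01 (adjusted p = 0.59), with Cdkn1a at -0.31 (SE 0.159), Gabarapl1 at -0.28 (SE 0.15) and Gadd45a at -0.29 (SE 0.162).

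Genes of energy metabolism and of the contractile apparatus had medians of opposite sign in the 2 batches, a difference that was not tested and that rests on 1 array a genotype in the replicate 1 pair. Genes of fatty acid uptake and oxidation had a median of -0.15 in the replicate 1 pair and 0.19 in replicates 2 and 3. Those of the respiratory chain had -0.37 and 0.11, those of the sarcomere -0.37 and 0.15, and those of glucose uptake and glycolysis -0.10 and 0.15. Heat shock genes had -0.09 and 0.20. Pooled over all arrays, the camera adjusted p of these 5 lists was 0.38, 0.59, 0.97, 0.59 and 0.38. In replicates 2 and 3 alone they were called higher, with 0.00015, 0.017, 0.017, 0.010 and 0.020, and each had an adjusted p = 0.85 with an estimated correlation. Without wild type replicate 1, 4 of them passed as higher: fatty acid 0.21 (adjusted p = 0.000723), respiratory chain 0.20 (0.00198), sarcomere 0.27 (0.00107) and glycolysis 0.20 (0.00255). Without wild type replicate 2 the respiratory chain passed as lower (-0.21, 0.00102), and without knockout replicate 1 heat shock passed as higher (0.24, 0.0104). Each fit without an array leaves unequal shares of the batches in the genotypes. The calls of those fits cannot be told apart from the batch difference. Single members did not pass: Slc2a4, the insulin-responsive glucose transporter, had 12720 ± 1050 against 10870 ± 1990 (log2 0.24, SE 0.192), and Pdk4 had -0.42 (SE 0.263). The tricarboxylic acid cycle genes had a median of 0.00 (adjusted p = 0.97), with Dlat at 0.13 (SE 0.155).

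**Figure D3:**
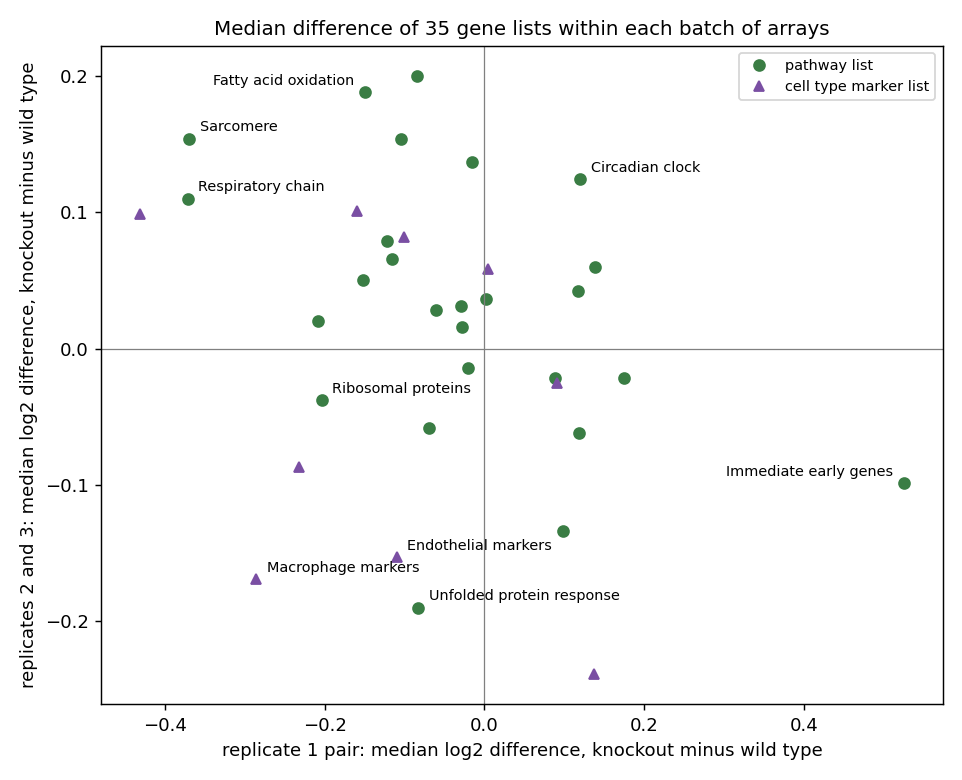
Median log2 difference, knockout minus wild type, of each of the 35 gene lists in the replicate 1 pair (horizontal axis) and in replicates 2 and 3 (vertical axis), with circles for pathway lists and triangles for marker lists. The sarcomere and respiratory chain lists lie at -0.37 on the horizontal axis and at 0.15 and 0.11 on the vertical one, while the macrophage list lies below 0 on both, at -0.29 and -0.17.

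Rab4a and the genes of beta-adrenergic signalling were listed with a known report on such mice in mind, so their lists are not independent evidence. The beta-adrenergic list had 16 of 23 members higher, with a median of 0.06 (camera adjusted p = 0.97) and no member with an unadjusted p under 0.05. The lowest were Arrb1, beta-arrestin 1 (log2 -0.28, SE 0.191), and Adra1b (-0.33, SE 0.25). Of the 22 tested Rab GTPases and partners of vesicle recycling, Rab4a alone rose adjusted over the list alone (adjusted p = 0.0444, and 0.0185 with the batch block), and the list had a median of -0.01 (adjusted p = 0.97). Calcium handling genes were higher in 14 of 19, with a median of 0.09 (adjusted p = 0.29). Without wild type replicate 1 the calcium handling median was 0.19 and passed (adjusted p = 0.0242), and it was -0.05 without wild type replicate 2 and 0.003 without knockout replicate 1. Casq1, a calsequestrin, had 787.8 ± 175 against 386.5 ± 201 (log2 1.09, SE 0.375), and Cacna2d1 had 0.38 (SE 0.156). Among ion channels (median 0.08, adjusted p = 0.89), Kcnd3 had 0.41 (SE 0.158) and Kcne1 -0.76 (SE 0.324). Of the fetal and hypertrophic programme (median -0.03, adjusted p = 0.97), Nppb, the natriuretic peptide of the strained ventricle, had 18780 ± 2240 against 26480 ± 4390 (log2 -0.49, SE 0.196), and Myh7 had 0.66 (SE 0.399).

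The remaining pathway lists did not pass with all arrays. Circadian clock genes were higher in 16 of 20, with a median of 0.145 (adjusted p = 0.13), led by Cry1 at 0.43 (SE 0.261). Without knockout replicate 1 the circadian list passed at 0.144 (adjusted p = 0.0414), and without wild type replicate 1 its median was 0.05. Antioxidant genes had a median of -0.08 (adjusted p = 0.38), with Hmox1, haem oxygenase 1, at -0.85 (SE 0.361). Extracellular matrix genes had 0.04 (adjusted p = 0.97), with Fn1 at 0.48 (SE 0.217). Apoptosis regulators had 0.02 (adjusted p = 0.97), with Bid at -0.66 (SE 0.198) and Bcl2 at 0.61 (SE 0.255). Autophagy genes had -0.05 (adjusted p = 0.41), sterol and lipid synthesis 0.05 (0.83), hypoxia -0.01 (0.97), interferon and antigen presentation 0.05 (0.97), cell cycle 0.05 (0.46), and proteasome and muscle atrophy 0.00 (0.97). Among their members, Igtp, an interferon-inducible GTPase, had 0.89 (SE 0.288) and Cyp51 had -0.69 (SE 0.264).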

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

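The batch block, the fit of replicates 2 and 3 alone, and the batch block with the trended, robust variance were chosen after seeing the data. Akt2 kept its direction under all 18 alternatives run for it (log2 between -2.91 and -2.45, adjusted p between 0.000849 and 0.567) and passed 0.05, at -2.69, with a stricter filter, with the trended, robust variance and with that variance plus the batch block. The 20 other named genes kept their sign in all 353 values. All but Akt1 and Rab4a were picked for a low p and a 1.5-fold difference in these same arrays. The blocks and the variance estimate cannot change a log2 difference with all arrays. The count of signs is therefore no measure of robustness. Changed genes, 0 in the main test, were 2 with the stricter filter, 1 with the trended, robust variance, 2 at a threshold of 0.10, 1 with the batch block and 5 with both. Changed probe sets, also 0, were 1 with the batch block and 13 with both. Probe sets with an unadjusted p under 0.01 and a 1.5-fold difference, 70, were 190 with no filter, 38 with the stricter filter (fewer were tested), 44 with the trended, robust variance, 194 with the replicate block, 234 with the batch block, 332 in replicates 2 and 3, 195 with the batch block and that variance, and 44 to 168 leaving out an array. Changed lists, 1, were 2 with the 40th percentile as pseudocount, 0 with no filter, 4 with the stricter filter, 3 after quantile normalization, 3 with the replicate block, 0 with an estimated correlation, 0 by fry, 4 with the batch block with or without the trended variance, 8 in replicates 2 and 3, and 0 to 7 leaving out an array: 7 without wild type 1, 2 without wild type 2, 0 without wild type 3, 3 without knockout 1 and 4 without knockout 3. The respiratory chain list, -0.05 and not called, was called higher without wild type replicate 1 (0.198) and in replicates 2 and 3 (0.110), and called lower without wild type replicate 2 (-0.215). The fits without an array leave unequal shares of the batches in the genotypes, so their calls mix in the batch difference. The causes were not tested. Of 697 other tests of the lists, 579 kept the direction of the camera test and the call, 81 turned that direction without a call, 31 passed anew and 4 no longer passed. By sign, 598 of the 697 medians stayed as in the main test. Each block is balanced over the genotypes, so the blocks, the variance estimate and the choice of list test leave every median unchanged. The list tests do not use the trended, robust variance, so under it they repeat the results without it. Part of the kept medians and calls was thus fixed in advance. The replicate block changed no call other than those of the macrophage and endothelial lists.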

Other observations

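The tests of sample preparation, RNA degradation, donor segments elsewhere, a lower share of other cells and the batch split of the markers, and every test with the batch block, within a batch or on splits balanced over the batches, were chosen after the results were seen.

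Immediate early genes were higher in 15 of 23 members with a median log2 difference of 0.13 (camera adjusted p = 0.38), but 0.53 in the replicate 1 pair and -0.10 in replicates 2 and 3. Without knockout replicate 3 the immediate early list passed as higher at 0.283 (adjusted p = 0.00876). The nuclear receptors Nr4a1 and Nr4a2 were higher in both batches. Nr4a1 had 3702 ± 2150 (SD, n = 3) in the knockout against 1476 ± 800 in the wild type (log2 1.30, SE 0.494), with 1.38 and 1.27 in the 2 batches. Nr4a2 had 463.6 ± 359 against 125.7 ± 81.6 (log2 1.70, SE 0.657). Egr3 had -0.78 (SE 0.285). Over the list alone the adjusted p of these 3 was 0.284 without a block, and with the batch block Nr4a1 passed (0.00644). Myl1, a myosin light chain in the skeletal muscle list, also passed over its list with that block (0.029), at 6268 ± 1440 against 3589 ± 1680. Dnajb1, a heat shock co-chaperone, had 2872 ± 857 against 1743 ± 363.

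5 marker lists had too few tested members for a list test. Of the sex-specific genes 4 were tested, with Y-linked Eif2s3y at 945.3 ± 331 in the knockout against 1209 ± 203, and Xist, the transcript of the inactive X chromosome, near the filter at 105.5 ± 83.1 against 111.8 ± 29.6 in these male mice. Of the erythroid genes 4 were tested, with Alas2 at 1096 ± 328 against 1491 ± 854. Lymphocytes and epicardium had 2 each and lung epithelium 0.

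The separation of the replicate 1 arrays was compared with 2 technical explanations. Their median poly-A control signal was 0.0832 times that of the other 4, but the batch was found from these same control probe sets, so this does not test whether target preparation differed. Degraded RNA in these hearts was left open: the highest 3′ to 5′ ratio of the Actb and Gapdh controls was 1.67, below the 3 that was asked for but above the 1.48 of the other arrays. Both stay open. No biological explanation was tested, since both genotypes are in each batch.

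Blvrb, among the genes with the lowest unadjusted p in limma besides Akt2, neighbours Akt2 in assembly GRCm38.p6. Chromosome carried along from the donor of the targeted allele may therefore account for part of the genes with a low p. Within 20 Mb of Akt2, 2 of 298 genes (Blvrb and Zfp975) had an unadjusted p under 0.01, against 44 of 10749 elsewhere (odds ratio 1.64, 95% interval 0.192 to 6.35, Fisher's exact p = 0.353, two-sided), which is too wide to decide; with the batch block the ratio was 0.847. For donor segments elsewhere, 2 pairs of such genes lay within 1 Mb of each other, Meox1 with Rnd2 and Nnt with Tmem267, against a median of 1 in 10000 random sets (permutation p = 0.483), which leaves this open too. Part of Nnt is deleted in the C57BL/6J substrain, the labels give no substrain, and whether the Nnt alleles of the groups differed was not tested. An effect of Akt2 loss on these genes remains open beside them.

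The lower macrophage and endothelial markers had a pooled median of -0.164 over 33 genes. A lower share of all cells other than myocytes needs fibroblast and smooth muscle markers to be lower alike, and their median over 26 genes was 0.024 (95% bootstrap interval over genes -0.061 to 0.088). Taken again without each array in turn, that interval lay above the macrophage and endothelial median in 3 of 6 cases, but not without wild type 2, wild type 3 or knockout 1, so this stays open. These differences of means have no batch term and leave unequal shares of the batches in the genotypes, so they mix in the batch difference. The 2 lists were picked for this test with their within-batch medians partly seen, so those medians, -0.188 in the replicate 1 pair and -0.155 in replicates 2 and 3, do not test the batch split, and the endothelial interval in the latter reached 0.001. Without knockout replicate 1 the macrophage median was 0.03, but wild type 1 then had no knockout of its batch beside it. Within the batches that median was -0.29 in the replicate 1 pair and -0.17 in replicates 2 and 3. Fewer such cells, or lower expression in them, are hypotheses that were not tested.

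The 6 arrays make 10 splits into groups of 3, too few for a share under 0.05. For changed probe sets and changed genes, all 10 splits, the real one included, gave as many as the real 0, with 0 the highest of the others. For probe sets with an unadjusted p under 0.01 and a 1.5-fold difference, 5 gave as many as the real 70, the real one included, and the highest of the others was 476. The 4 splits that put both replicate 1 arrays on the same side gave 216, 248, 315 and 476, which restates the separation of these arrays as a structure of the samples. Of the 4 splits that part every replicate pair, the real one had 70 and the highest of the others 27; with the batch block, over 6 balanced splits, these were 234 and 166. For changed lists all 10 splits, the real one included, gave as many as the real 1, with 7 the highest of the others, and with the batch block the real split had 4 and the highest of the others 8.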
